A study of Mus musculus with 6 samples.

How the data were processed

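Total RNA from a piece of liver lobe of 6 mice, 3 fed the diet 10C and 3 fed 6C+4CP, was measured on 1 array each. Per the labels' protocols, the tissue was kept in RNAlater, total RNA was isolated and column-purified, and biotin-labelled amplified RNA was made from 100 ng of it with an Affymetrix 3' IVT Express kit. Samples were grouped by their titles, which also carry replicate numbers 1 to 3, and each array is a separate mouse per the labels.

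The only values used were the authors' processed values in the deposited table of the series, 1 column per array, which are on a log2-like scale. Per the submitters' processing notes, R 2.7.2 was used. The background correction, summarisation and log base are not given in the sources used here. The values were read as log2 because they run from 4.76 to 14.48 with medians from 6.306 to 6.308 over the arrays, and they were used as deposited. No signal over background is given with these values, so their precision rests on the 3 mice per diet alone.

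The table holds 45101 probe sets, of which 64 Affymetrix controls were left out of the tests, leaving 45037. GEO's platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160, and a probe set with several symbols named no gene. The symbols were compared through Entrez identifiers with a reference gene table, which held 34741 of them and changed 0. For the account of genes the probe set with the highest mean over the 6 arrays stood for each of 18193 genes, and the directions of a named gene's other varying probe sets were checked. No genome build is named in the files, so positions are not given.

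Diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, all 6 arrays, no covariates), with Benjamini-Hochberg adjusted p under 0.05 as the threshold, over probe sets and over genes. Differences are 6C+4CP minus 10C in mean log2 value, so a fold is a ratio of geometric means. Gene lists were tested with limma's camera, two-sided, at a preset correlation between genes of 0.01, adjusted over all 37 lists, and lists with under 5 measured members were not tested. The counts adjusted over the list alone use the same limma p with Benjamini-Hochberg adjustment within the list, and were repeated with the p of the fit to varying genes after the data were seen. Array controls were compared by two-sided exact permutation tests, whose smallest p for 3 against 3 is 0.1.

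The lists cover 23 processes and 14 cell types and hold 734 symbols, of which 661 had a probe set, 8 through an older symbol. The processes are cholesterol synthesis; fatty acid and triglyceride synthesis; fatty acid oxidation and PPARa targets; lipid droplets and lipid uptake; lipoproteins; bile acid synthesis and sterol transport. Further ones are endoplasmic reticulum chaperones and the unfolded protein response, the ATF4 and amino acid response, urea cycle and amino acid catabolism, glycine, proline and hydroxyproline metabolism, and glucose metabolism and insulin or IGF signalling. The rest are xenobiotic metabolism, oxidative stress and metallothioneins, acute phase, interferon and antigen presentation, circadian clock, male-biased and female-biased liver genes, extracellular matrix and collagen processing, cell cycle, cytosolic ribosome, mitochondrial respiratory chain, and the immediate early and handling response. The cell types are hepatocytes with their pericentral and periportal kinds, Kupffer cells and macrophages, sinusoidal endothelium, stellate cells, cholangiocytes, B cells, T or NK cells, neutrophils, erythroid cells, pancreatic acinar cells, adipocytes and skeletal muscle.

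The grouping, the tests, the lists, the rule for named genes and the alternative settings, apart from those on varying probe sets, were fixed before the data were examined. By that rule the text names the 10 genes with the largest rise and the 10 with the largest fall among called genes without overlap, filled up by smallest p, up to 4 members of each process list and up to 3 of each cell type list by smallest p, passing over unnamed predicted genes. The shrunken genes it picked are given by count and example. Because most deposited values were shared by all arrays, an account of probe sets ranging over more than 0.01, and the same rule on their genes, was added after seeing the data. Vnn1, Acot1, Acot3, Cyp4a14, Creld2, Sdf2l1, Syvn1, Hyou1, Cyp7a1, Cyp8b1, Acaca, Elovl6, Me1, Saa1, Dbp, Arntl, Nfil3, Thrsp, Srebf1, Fdps, Lpin1, Igfbp1, Got1, Asl, Hspa1b, Igtp, Cd22, Slc25a20, Abcc3, Abcg8, Socs3, Gulo, Hal, Nnmt and Egfr were also chosen after their values were seen, as were the other called members and the higher members of the endoplasmic reticulum list and Col1a1.

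The alternatives were the replicate number as a block, leaving out each array in turn, quantile normalization, median centring, the brighter part of the probe sets, an intensity trend with robust estimation, a minimum fold of 1.2, an adjusted p under 0.1, a plain test without moderation, and the rank product of 9 pairwise ratios with 1000 permutations. For genes and lists these were joined by the mean of a gene's probe sets, leaving out ambiguous probe sets, an estimated correlation, fry and ranks. Alternatives on varying probe sets were added after seeing the data. Rank product counts for lists and named genes come from its run over all 18193 genes, which the simulation below did not cover. The rank product and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

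The steps were tested on simulated data built from these arrays. In the fit over all 18193 genes the changed genes were drawn only from those with varying values. There limma recovered 51% of genes changed by 1 and 84% of genes changed by 2 on the log2 scale, with 2 false calls. Values shared by all arrays were simulated as independent noise and not as differences in the last stored digits. The 2 false calls thus do not describe calls of such genes, which make up 42 of the 46 in the real fit. Over the 5057 genes with a varying probe set limma recovered 84% and 93% with 13 false calls, and the rank product 89% and 100% with 17 false calls. Camera on those genes recovered the 1 list shifted by -0.5 and called 0 others of the 27 lists simulated. Simulated genes were drawn independently of each other. The list result therefore does not show how often camera calls lists falsely when members move together.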

Results

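Liver gene expression was measured in 6 male BALB/cCrSlc mice, an inbred albino laboratory strain, to ask how collagen peptide in the diet changes hepatic gene expression. All mice ate low-protein diets built on AIN-93M, a purified maintenance diet for adult rodents. The control diet, named 10C, held 10% casein. The diet named 6C+4CP held 6% casein and 4% collagen peptide from fish, a hydrolysate rich in glycine, proline and hydroxyproline. Less casein and added collagen peptide came together, so their effects cannot be told apart here. The diets were fed for 10 weeks, and a piece of liver was taken in the morning at 17 weeks of age after 3 h without food. Each diet was given to 12 mice, of which 3 with medium food efficiency (weight gained per food eaten) were used, so the labels make the 3 arrays of a diet 3 separate mice. The design text counts 3 groups of mice, and the third is not analysed here.

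Each mouse gave 1 Affymetrix 3' expression array with 45037 tested probe sets, which represent 18193 genes. The median deposited value lay between 6.306 and 6.308 on the 6 arrays, and the number of arrays limits the precision. The values behave as logarithms and are treated as log2 here, although their base is not given in the sources used here, so every fold value below rests on that reading. Most probe sets hold 1 value shared by all mice: 37246 of the 45037 ranged over at most 0.01, and 7791 (17.3%) ranged over more. The share that varied was 4.67% among the dimmest and 46.9% among the brightest of 4 groups of probe sets of equal size. A gene whose values are shared in this way is called shrunk below, and its value does not show whether its level differed between the mice.

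Livers of mice fed 6C+4CP had lower values of endoplasmic reticulum chaperone genes and higher values of fatty acid oxidation genes than livers of mice fed 10C. Among 37 gene lists fixed before the data were examined, 6 passed the test between the diets. The 2 higher lists were fatty acid oxidation with PPARa targets, and lipid droplets with lipid uptake. The 4 lower lists were endoplasmic reticulum chaperones with the unfolded protein response, interferon with antigen presentation, urea cycle with amino acid catabolism, and lipoproteins. These calls come from limma's camera with a preset correlation between genes, and with an estimated correlation camera called 0 of 37 lists, with 2 at an unadjusted p under 0.05. On all genes the self-contained test fry called 1 list for a shift in 1 direction, as higher. It was the extracellular matrix list, which is not among the 6 (adjusted p = 0.0436). Of its 32 measured members 24 were shrunk, and on varying genes alone fry called 1 list, as lower. For the 6 lists fry on all genes gave 0.0914 (endoplasmic reticulum), 0.193 (fatty acid oxidation), 0.139 (lipid droplets), 0.0914 (interferon), 0.149 (urea cycle) and 0.384 (lipoproteins). For change in either direction it called 11 lists, among them the endoplasmic reticulum, interferon and urea cycle lists. Across varying probe sets, 10C replicate 3 correlated more closely with 6C+4CP replicate 2 (r = 0.985, across probe sets, which are not independent replicates) than with the other mice of its own diet (0.971 and 0.973).

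**Figure D1:**
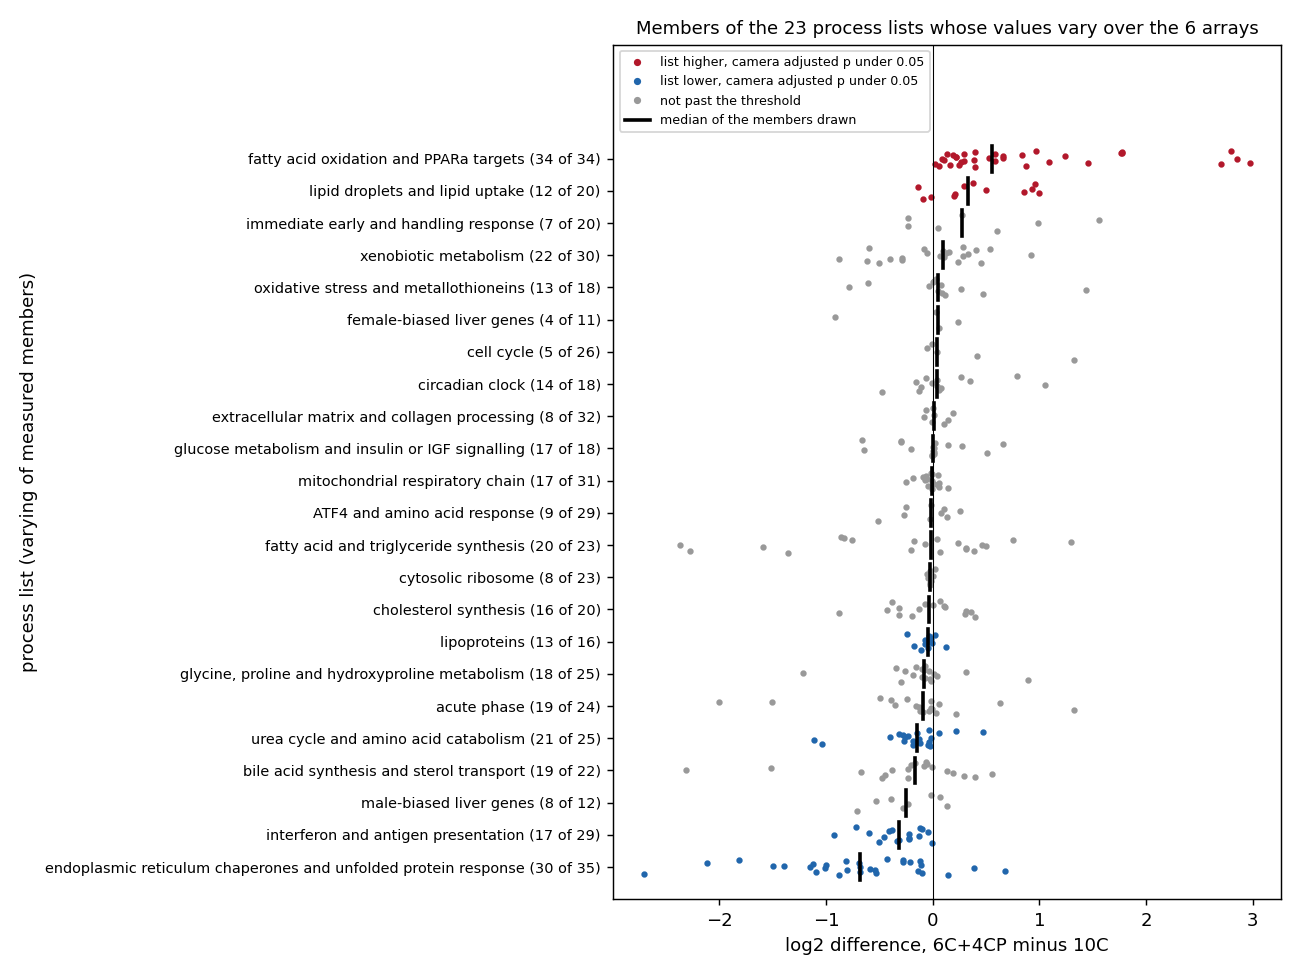
Each point is a member gene of a process list whose values vary over the 6 arrays, at its log2 difference, 6C+4CP minus 10C, with the median of the members drawn as a black bar and the varying and measured members counted in parentheses. The endoplasmic reticulum list has the lowest median (-0.68) and the fatty acid oxidation list the highest (0.56).

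Genes of endoplasmic reticulum protein folding were lower in 6C+4CP. Of the 35 members measured, 30 varied, 27 of them lower and 3 higher. Hspa5, the chaperone BiP that binds unfolded proteins, had a value of 12.96 ± 0.25 (SD, n = 3) in 10C and 11.81 ± 0.035 in 6C+4CP, a log2 difference of -1.15 (SE 0.14) or 2.22 times lower. The widest gap was that of Creld2, an endoplasmic reticulum protein induced by stress there, with a difference of -2.71 (SE 0.50). The list as a whole passed camera (adjusted p = 2.07e-12, median difference -0.54 over measured and -0.68 over varying members). The call was lost with another treatment of the genes' dependence (adjusted p = 0.377 with an estimated correlation).

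Adjusted over the list alone, 13 members of this list fell and 22 did not pass, and over all genes tested 1 member, Edem1, passed. The 13 were Edem1, Hspa5, Dnajc3, Manf, Creld2, Dnajb11, Pdia4, Sdf2l1, Syvn1, Pdia3, Ero1b, Sel1l and Hyou1. They include Manf, a secreted factor induced by endoplasmic reticulum stress, which fell by 1.49 (SE 0.26), and Dnajc3, a co-chaperone of BiP, which fell by 0.80 (SE 0.11). Sdf2l1, found in chaperone complexes, fell by 2.12 (SE 0.41), and Syvn1, a ubiquitin ligase of endoplasmic reticulum associated degradation, fell by 1.82 (SE 0.36). The 3 mice of a diet lay apart from the 3 of the other in 19 lower and 2 higher members, against 10% expected by chance and 19.8% among all genes with a varying probe set. The rank product, run here and for the lists below over all 18193 genes with the shrunk ones included, called 19 members lower and 1, Dnajb9, higher. That run called 380 genes, against 98 when only genes with a varying probe set were ranked. On genes with varying values alone, 18 members passed adjusted over the list alone, 16 lower and 2 higher, Herpud1 and Atf6. The 3 higher members, none of which passed limma with all genes, were Dnajb9 with a difference of 0.68 (SE 0.53), Herpud1 with 0.39 (SE 0.13) and Atf6, a sensor of unfolded proteins, with 0.15 (SE 0.043). Without any 1 mouse the list kept its call, with adjusted p between 4.93e-12 and 7.58e-08, and over its 26 alternatives p ran from 1.8e-23 to 0.428. The 10C mouse with the highest Hspa5 value, replicate 2 with 13.25, was also the mouse with the highest Saa1 value (14.03, against 7.54 to 9.13 in the other mice), the acute phase protein serum amyloid A. Without that mouse Hspa5 and Sdf2l1 passed over all genes (adjusted p = 0.0195 for each), with differences of -1.01 and -1.70, and Edem1 did not. That fit includes shrunk genes and called 160 genes.

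**Figure D2:**
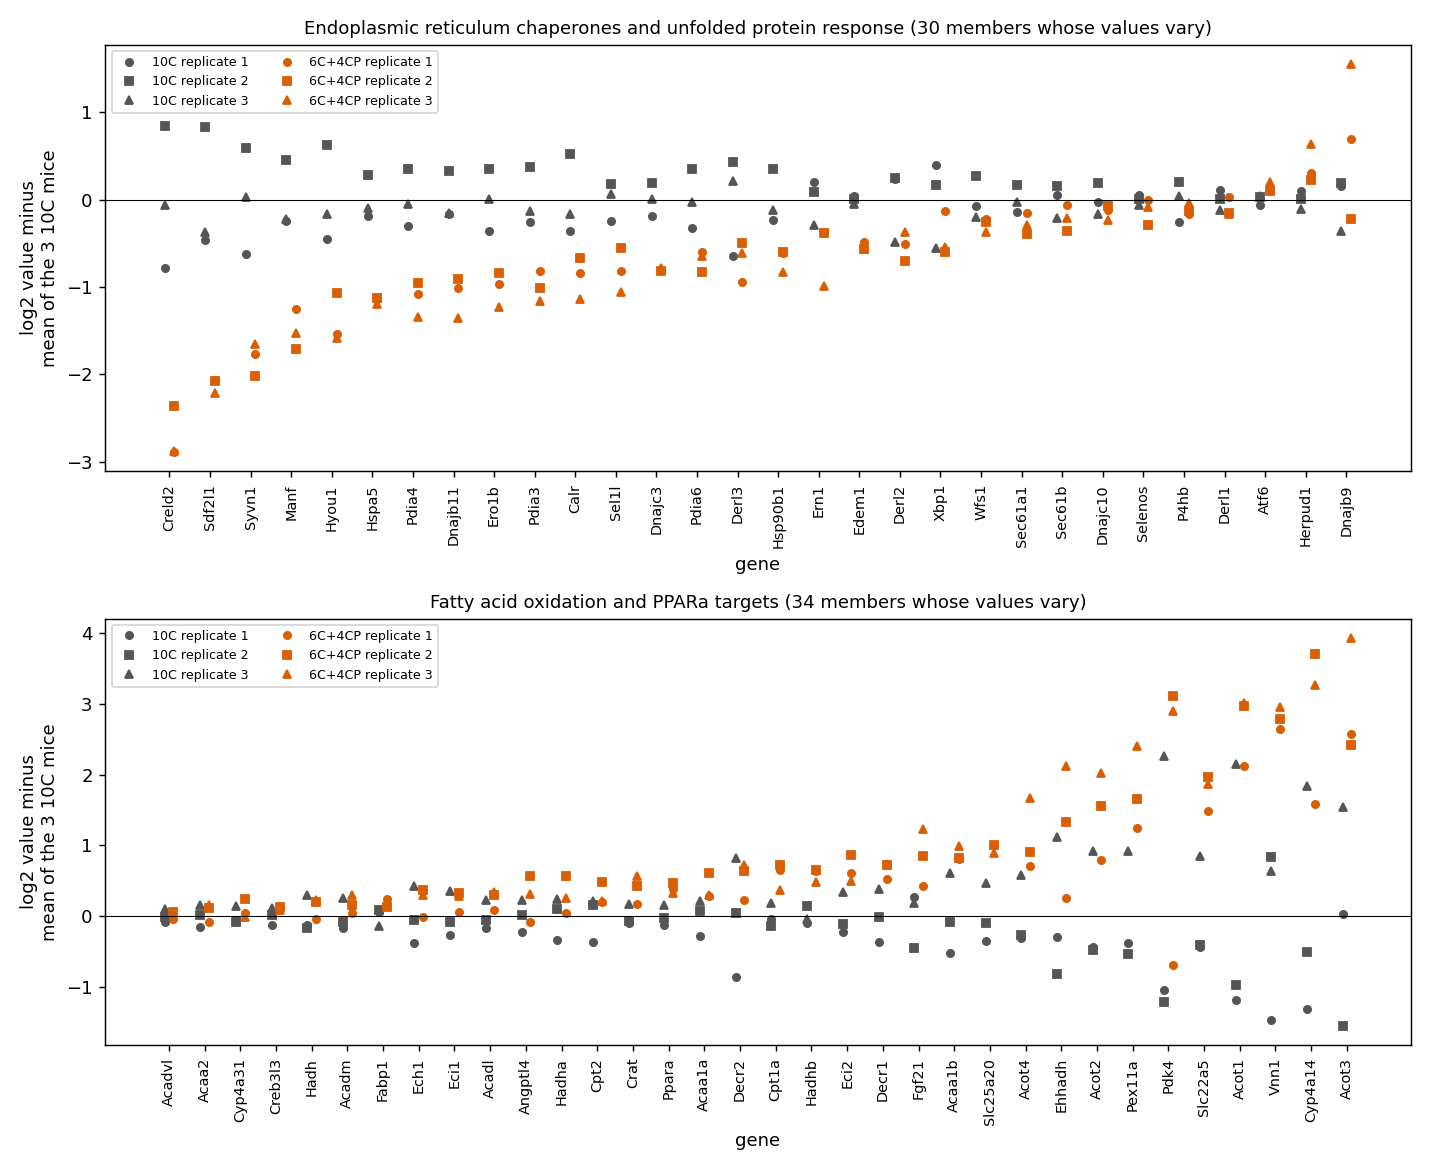
Points give each mouse's log2 value minus the mean of the 3 mice fed 10C (y axis) for each varying member (x axis) of the endoplasmic reticulum list (top) and of the fatty acid oxidation list (bottom), with 10C in grey, 6C+4CP in orange and replicates 1 to 3 as circle, square and triangle. Of the 30 members in the top panel 27 had a lower mean in 6C+4CP, and all 34 in the bottom panel had a higher one.

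Genes of fatty acid oxidation were higher in 6C+4CP. All 34 members measured varied, 34 higher and 0 lower. Vnn1, the pantetheinase vanin, a target of the lipid-sensing receptor PPARa, had a value of 7.35 ± 1.27 (SD, n = 3) in 10C and 10.15 ± 0.15 in 6C+4CP, or 6.96 times higher (log2 difference 2.80, SE 0.73). Without 10C replicate 1, the mouse with the lowest Vnn1 value (5.88), that difference was 2.07. Hadhb, a subunit of the mitochondrial trifunctional protein of fatty acid oxidation, differed by 0.59 (SE 0.090). Cpt1a, which admits fatty acids to mitochondrial oxidation, differed by 0.58 (SE 0.14), Ppara, the receptor itself, by 0.39 (SE 0.094), and Slc22a5, the carnitine transporter, by 1.77 (SE 0.44). The list passed camera (adjusted p = 4.1e-12, median difference 0.56), but not with the other treatment of dependence (adjusted p = 0.532 with an estimated correlation).

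Adjusted over the list alone limma called 0 members of this list, with 0 over all genes. The rank product over all genes, shrunk ones included, called 17 higher and 0 lower. Among genes with varying values alone, 6 members passed as higher adjusted over the list alone, Hadhb, Slc22a5, Cpt1a, Slc25a20, Ppara and Vnn1. In 16 members the 3 mice of a diet did not overlap the 3 of the other, against 10% by chance and 19.8% of all varying genes. Spread within the 10C diet was wide for the genes with the widest gaps. Acot1, a thioesterase of long-chain acyl-CoA, read 6.91, 7.12 and 10.25 in the 10C mice and 10.21, 11.07 and 11.11 in the 6C+4CP mice. Its mean was 6.51 times higher in 6C+4CP (SE 1.10 in log2), and the log2 difference was 2.98 (SE 1.00) for Acot3 and 2.86 (SE 1.13) for Cyp4a14, a fatty acid hydroxylase. The 10C mouse inside the range of the other diet was replicate 3, and without it the difference of Acot1 was 3.78, against 2.11 without 10C replicate 1, and that of Slc22a5 was 2.19. Both passed without that mouse among the genes with varying values (adjusted p = 0.0454 for each). The list kept its call without any 1 mouse, with adjusted p between 1.54e-17 and 3.43e-07, and over its 26 alternatives p ran from 1.57e-53 to 0.556.

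The lipid droplet and lipid uptake list was also higher, with 9 of its 12 varying members higher and 3 lower, out of 20 measured. Plin2, a coat protein of lipid droplets, differed by 0.93 (SE 0.30), Fitm2, which acts in droplet formation, by 0.99 (SE 0.34), and Pnpla2, the triglyceride lipase ATGL, by 0.37 (SE 0.079). Of its members limma called 0 adjusted over the list alone and 0 over all genes, the rank product called 4 higher, and 5 did not overlap between the diets (10% by chance, 19.8% of all varying genes), all higher. The list passed camera (adjusted p = 0.00636, median difference 8.3e-09 over measured and 0.33 over varying members, mean 0.25 over measured members), which was lost by another treatment of dependence (adjusted p = 0.377 with an estimated correlation). Without 6C+4CP replicate 3 the adjusted p was 0.0656, and over 26 alternatives it ran from 8.84e-08 to 0.428.

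Interferon and antigen presentation genes were lower in 6C+4CP: 17 of 29 measured members varied, 0 higher and 17 lower. Irgm1, an interferon-induced GTPase, differed by -0.60 (SE 0.15), its relative Igtp by -0.92 (SE 0.46), or -0.49 without 10C replicate 2, and the class I histocompatibility gene H2-D1 by -0.31 (SE 0.095). That mouse, the one with high Saa1, had the highest value of both Irgm1 (8.58) and Igtp (10.10). H2-Ab1, of class II, which macrophages and B cells also express, differed by -0.34 (SE 0.11). Of 9 varying Kupffer cell and macrophage markers 7 were lower, all with overlap, and 2 higher, among them Slc40a1, an iron exporter, by 0.26 without overlap (0.13 without 10C replicate 2). Their median of -0.19 rested on single mice, with -0.30 without 10C replicate 2, -0.012 without 10C replicate 3, -0.064 without 6C+4CP replicate 2 and -0.37 without 6C+4CP replicate 3. Of the 2 varying B cell markers Ighm differed by -0.66 without overlap and Cd22 by 0.050. Neither the Kupffer cell nor the B cell list was called (adjusted p = 0.414 for each), but the Kupffer cell list was called as lower with the replicate number as a block (0.0153) and without 6C+4CP replicate 3 (0.0128), with 0.00564 to 0.97 over 26 alternatives. Camera called the list (adjusted p = 2.54e-05, median difference -0.098 over measured and -0.31 over varying members), and not with the other treatment of dependence (adjusted p = 0.215 with an estimated correlation). Limma called 0 members adjusted over the list alone and 0 over all genes, the rank product called 4 lower, and 7 lower members did not overlap between the diets (10% by chance, 19.8% of all varying genes). The list kept its call without any 1 mouse, with adjusted p between 2.99e-05 and 0.00175, while its median over measured members was -0.061 without 10C replicate 1 and -0.046 without 6C+4CP replicate 1, and over 26 alternatives p ran from 8.89e-08 to 0.276.

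Genes of the urea cycle and amino acid catabolism were lower by smaller amounts, with 18 of 21 varying members lower and 3 higher, out of 25 measured. Cps1, the first enzyme of the urea cycle, read 13.36 ± 0.061 (SD, n = 3) in 10C and 13.10 ± 0.038 in 6C+4CP, a difference of -0.27 (SE 0.041). Asl, a later enzyme of the cycle, differed by -1.04 (SE 0.36), Got1, the cytosolic aspartate aminotransferase, by -1.11 (SE 0.45), and Hgd and Kmo, of tyrosine and tryptophan breakdown, by -0.40 (SE 0.12) and -0.32 (SE 0.093). The list passed camera (adjusted p = 0.0225, median difference -0.12), but not with the other treatment of dependence (adjusted p = 0.377 with an estimated correlation). Limma called 0 members adjusted over the list alone and 0 over all genes, the rank product called 2 lower, and 8 lower members did not overlap between the diets (10% by chance, 19.8% of all varying genes). Cps1 passed adjusted over the list alone when only genes with varying values were tested. The call was lost without 10C replicate 3 (adjusted p = 0.065, median -0.055) or 6C+4CP replicate 1 (0.201, median -0.071), the median was -0.053 without 10C replicate 1, and over 26 alternatives p ran from 0.000539 to 0.428.

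Lipoprotein genes differed by little, with 11 of 13 varying members lower and 2 higher, out of 16 measured. Apoh, a plasma phospholipid-binding apolipoprotein, fell by 0.070 (SE 0.0099) adjusted over the list alone, the 1 member to do so, and 0 passed over all genes by limma, with 0 by the rank product. That call ended among genes with varying values alone (Apoh, adjusted p = 0.397 over the list alone). Apoa1, the main protein of high-density lipoprotein, differed by -0.11 (SE 0.024), and 3 of the 13 varying members, all lower, did not overlap between the diets (10% by chance, 19.8% among all genes with a varying probe set). The list passed camera (adjusted p = 0.0463, median difference -0.029), and not with the other treatment of dependence (adjusted p = 0.618 with an estimated correlation). The call was lost without 10C replicate 2 (adjusted p = 0.184), 10C replicate 3 (0.356) or 6C+4CP replicate 1 (0.0784), and on genes with varying values alone (0.191). The median moved to -0.078, -0.048 and -0.0066 without 10C replicates 1, 2 and 3, and to -0.011 and -0.055 without 6C+4CP replicates 1 and 2. Over 26 alternatives p ran from 0.0271 to 0.836.

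Bile acid genes included some of the widest gaps but did not pass as a list (adjusted p = 0.0586, 14 of 19 varying members lower and 5 higher, median -0.17, or -0.11 without 10C replicate 2 and -0.089 without 6C+4CP replicate 2 on varying genes). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 9.06 ± 0.36 (SD, n = 3) in 10C and 6.74 ± 0.94 in 6C+4CP, a difference of -2.31 (SE 0.57) without overlap. Cyp8b1, which makes cholic acid, differed by -1.52 (SE 0.89; -1.01 without 10C replicate 3), Cyp27a1, the mitochondrial sterol hydroxylase, by -0.38 (SE 0.063), and Acox2, a peroxisomal oxidase of bile acid side chains, by -0.67 (SE 0.16). Limma called 0 members adjusted over the list alone and 0 over all genes, and the rank product called 1 higher and 5 lower. Among genes with varying values alone, 5 members passed adjusted over the list alone, with Cyp7a1, Cyp27a1, Acox2 and the transporter Abcc3 lower and the sterol transporter Abcg8 higher. Of the members that did not overlap between the diets (10% by chance, 19.8% of all varying genes), 6 were lower and 2 higher. The list passed without 10C replicate 1 (adjusted p = 0.017) or 6C+4CP replicate 3 (0.0473), among the brighter genes (0.0485) and with the mean of a gene's probe sets (0.0228), and over 26 alternatives p ran from 0.00467 to 0.684.

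Fatty acid and triglyceride synthesis genes went both ways, 10 higher and 10 lower among 20 varying members, and the list did not pass (adjusted p = 0.734). Fasn, the fatty acid synthase, read 8.59 to 11.49 in the 10C mice and 7.89 to 8.16 in the 6C+4CP mice, a difference of -2.37 (SE 0.88). Acly, which supplies acetyl-CoA for lipid synthesis, differed by -2.27 (SE 0.84), with 2 further varying probe sets of the gene lower and 2 higher. Acaca, the acetyl-CoA carboxylase, differed by -1.36 (SE 0.58) and the elongase Elovl6 by -1.59 (SE 0.77). On the other side stood Me1, the malic enzyme, with a difference of 1.29 (SE 0.61), and the desaturase Fads2 with 0.46 (SE 0.15). Limma called 0 members adjusted over the list alone and 0 over all genes, and the rank product called 4 higher and 7 lower. Without 10C replicate 3, the 10C mouse with the lowest Fasn value, the list passed as lower (adjusted p = 0.0298), and over 26 alternatives p ran from 0.0298 to 0.999. Without that mouse Fasn (difference -3.25, adjusted p = 0.0423) and Elovl6 (-2.36, 0.0454) passed among genes with varying values, while the difference of Me1 shrank to 0.75. Without 6C+4CP replicate 1 Fads2 passed over all genes (0.61, 0.0299), in a fit that includes shrunk genes and called 126 genes. Among genes with varying values alone no gene passed without that mouse.

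The cholesterol synthesis list did not pass either (adjusted p = 0.961), with 7 varying members higher and 9 lower. Hmgcs1, an early enzyme of the pathway, differed by 0.36 (SE 0.10) and Insig1, which restrains the pathway, by -0.43 (SE 0.27), or -0.20 without 10C replicate 1 and -0.66 without 10C replicate 3. Limma called 0 members adjusted over the list alone and 0 over all genes, and the rank product called 1 lower. Over 26 alternatives p ran from 0.113 to 0.998.

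Lists closest to the amino acids of collagen did not pass. Glycine, proline and hydroxyproline metabolism (adjusted p = 0.414) had 18 varying of 25 measured members, 4 higher and 14 lower. Glyat, which conjugates glycine to acyl groups, differed by 0.31 (SE 0.050), Gnmt, which methylates glycine, by -0.26 (SE 0.11; -0.17 without 10C replicate 1), and Gldc, of the glycine cleavage system, by -1.22 (SE 0.51). The ATF4 and amino acid response list (adjusted p = 0.734) had 20 shrunk of 29 measured members, among them Asns, the asparagine synthetase. Aars, the alanyl-tRNA synthetase now named Aars1, differed by -0.52 (SE 0.17). The extracellular matrix and collagen processing list (adjusted p = 0.642) had 24 shrunk of 32 measured members, and Col1a1, a chain of type I collagen, differed by -0.0085 (SE 0.019). In these 3 lists limma called 0, 0 and 1 members adjusted over the list alone and 0, 0 and 1 over all genes, and the rank product called 2, 1 and 0. The 1 called member, Mmp14, was shrunk and differed by 2e-09. Among genes with varying values alone 1 member of these lists, Glyat, passed adjusted over the list alone. The glycine list passed as lower on varying genes without 10C replicate 1 (adjusted p = 0.0442) or 6C+4CP replicate 3 (0.0116), and the extracellular matrix list passed fry for a shift in 1 direction (0.0436) and in either (3.6e-10). Over 26 alternatives p ran from 0.0116 to 0.949 for the glycine list, from 0.386 to 0.999 for the ATF4 list and from 3.6e-10 to 0.999 for the extracellular matrix list.

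The circadian clock list was not called (adjusted p = 0.0586), with 8 varying members higher and 6 lower. Usp2, a clock-controlled ubiquitin protease, rose by 0.79 (SE 0.066) adjusted over the list alone, the 1 member to do so, and 0 passed over all genes by limma, against 2 higher by the rank product. Tef, a clock output factor, differed by 0.27 (SE 0.066). The list passed as higher without 10C replicate 2 (adjusted p = 0.0371), under quantile normalization (0.00291), under median centring (8.1e-06) and among the brighter genes (0.046), and over 26 alternatives p ran from 8.1e-06 to 0.685. Median centring gave shrunk genes 1 shared difference of -0.00044, and camera sets a list against all other genes. A call as higher under that setting, here and in the lists below, may follow from this offset, which was not tested. Without 6C+4CP replicate 2 Usp2 passed over all genes (difference 0.73, adjusted p = 0.033), in a fit that includes shrunk genes and called 116 genes.

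Metabolic lists without a call were glucose metabolism with insulin or IGF signalling, xenobiotic metabolism (adjusted p = 0.734 for each) and oxidative stress with metallothioneins (0.254). Gys2, the liver glycogen synthase, rose by 0.51 (SE 0.066) adjusted over the list alone, the 1 member of the glucose list to do so, against 0 over all genes by limma and 2 higher and 2 lower by the rank product. In the xenobiotic list Cyp2c29, a drug-metabolising cytochrome, differed by -0.62 (SE 0.20) and Gstm2, a glutathione transferase, by 0.93 (SE 0.39). Gsta2, another such transferase, differed by 1.43 (SE 0.33) in the oxidative stress list. Limma called 0 members of the xenobiotic and oxidative stress lists adjusted over the list alone and 0 over all genes, and the rank product called 2 higher and 3 lower in the first and 1 each way in the second. All 3 lists passed as higher under median centring (adjusted p = 0.00603, 0.00343 and 0.000163 in the order named first), which may follow from the offset of shrunk genes in that setting. The oxidative stress list also passed as higher under quantile normalization (0.00192) and on varying genes without 10C replicate 3 (0.0423). Over 26 alternatives p ran from 0.00603 to 0.967, from 0.00343 to 0.974 and from 0.000163 to 0.733.

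Acute phase genes did not differ as a list (adjusted p = 0.621), and the mean of Saa1 was 0.249 of that in 10C (SE 1.98 in log2), with its high value in 1 of the 3 10C mice, without which, 10C replicate 2, the log2 difference of Saa1 was -0.082 (-3.26 without 10C replicate 1). Male-biased liver genes (adjusted p = 0.414) and female-biased liver genes (0.621) did not pass, and Fmo2, of the female-biased list, differed by -0.92 (SE 0.40), or -0.59 without 10C replicate 1. The cell cycle list (adjusted p = 0.734) had 21 shrunk of 26 measured members, and Ccnd1, cyclin D, differed by 1.32 (SE 0.41). Without 6C+4CP replicate 2 Ccnd1 passed over all genes (difference 1.73, adjusted p = 0.0481), in the fit with shrunk genes that called 116 genes. The immediate early and handling response list did not pass (adjusted p = 0.734), and Hspa1b, a heat shock protein, differed by 1.56 (SE 1.12), or 2.37 without 10C replicate 1 and 0.85 without 10C replicate 3. In these 5 lists limma called 0 members adjusted over the list alone and 0 over all genes, and the rank product called 2 higher and 2 lower, 0 and 2 lower, 0 and 1 lower, 1 higher, and 3 higher, in that order. Among genes with varying values alone 1 member, Socs3, a suppressor of cytokine signalling in the acute phase list, passed as higher adjusted over the list alone (0.99). No alternative called any of these 5 lists, the lowest adjusted p being 0.125, for the male-biased list. Cytosolic ribosome genes (adjusted p = 0.462) and mitochondrial respiratory chain genes (0.734) were lower by medians of -0.024 and -0.0089 over varying members, and under quantile normalization both lists turned higher and passed (adjusted p = 0.00192 and 6.33e-06). On varying genes without single mice the median ran from -0.035 to -0.012 for the ribosome and from -0.037 to 0.011 for the respiratory chain. Over 26 alternatives p ran from 0.00192 to 0.963 for the ribosome and from 6.33e-06 to 0.999 for the respiratory chain, and 0 members of either list were called adjusted over the list alone, over all genes by limma or by the rank product.

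None of the 14 cell type lists passed camera. The adjusted p was 0.642 for hepatocyte markers, 0.414 for pericentral and 0.642 for periportal hepatocyte markers. It was 0.414 for Kupffer cells and macrophages, 0.734 for sinusoidal endothelium, 0.977 for each of stellate cells, cholangiocytes and neutrophils, 0.414 for B cells and 0.178 for T or NK cells. For erythroid cells it was 0.983, and for pancreatic acinar cells, adipocytes and skeletal muscle 0.734 each. Adjusted over the list alone 1 member passed in each of the hepatocyte, pericentral, periportal and T or NK cell lists, against 1 of them over all genes, the shrunk T cell marker Cd2. The other 3 were Cps1, which fell by 0.27, Cyp27a1, which fell by 0.38, and Hsd17b13, a lipid droplet protein of hepatocytes, which rose by 0.20 (SE 0.021). Among genes with varying values alone Gulo (pericentral, -0.40), Hal (periportal, -0.26), Krt23 (cholangiocyte) and Ighm (B cell) also passed adjusted over the list alone. Without 6C+4CP replicate 3 the Kupffer cell list passed as lower (adjusted p = 0.0128), and over its 26 alternatives p ran from 0.00564 to 0.97. The pericentral list passed as lower on varying genes without 6C+4CP replicate 3 (0.0343; 0.0343 to 0.87 over 26 alternatives), and the adipocyte list as higher under median centring (0.0392; 0.0392 to 0.973 over 14). For change in either direction fry called the hepatocyte, periportal, stellate, T or NK cell and skeletal muscle lists. Among markers of other cells, Ighm, the immunoglobulin mu chain of B cells, differed by -0.66 (SE 0.17), and Krt23, a keratin of bile ducts, by 0.52 (SE 0.13). At its brightest probe set no marker of neutrophils, skeletal muscle or T or NK cells varied, and at another probe set 1 T or NK cell marker did, so these lists say little of the content of such cells.

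The sign of a list's test and of its mean differed in 8 lists. The ATF4, glucose and female-biased lists tested as higher with a negative mean, and the hepatocyte, stellate cell, cholangiocyte, T or NK cell and skeletal muscle lists as lower with a mean above 0. None of the 8 was called.

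Gene by gene, limma called 46 of 18193 genes, 23 higher and 23 lower in 6C+4CP. Of these, 42 were shrunk, with differences of at most 4e-09, such as Slc35f1 and Mmp14, and 4 varied. The 3 that rose were Spc25, a kinetochore subunit (1.62, SE 0.11, adjusted p = 0.0356), Sec23a, a coat protein of vesicles leaving the endoplasmic reticulum (0.53, SE 0.026, 0.0103), and Slc22a23, a member of a transporter family (0.23, SE 0.012, 0.0138). The 1 that fell was Edem1, which directs misfolded glycoproteins to degradation (-0.54, SE 0.036, 0.0381). Without single mice the differences moved little, from 1.54 to 1.71 for Spc25, 0.51 to 0.55 for Sec23a, 0.22 to 0.24 for Slc22a23 and -0.57 to -0.52 for Edem1, while the adjusted p crossed the threshold. Sec23a lost its call without 6C+4CP replicate 3 (adjusted p = 0.0586), and Slc22a23 without 10C replicate 1 (0.076), 10C replicate 3 (0.0767) or 6C+4CP replicate 2 (0.0582). Spc25 kept its call without 10C replicate 2 and lost it without 10C replicates 1 (0.0623) and 3 (0.139) and 6C+4CP replicates 1 (0.133), 2 (0.103) and 3 (0.118). Edem1 kept its call without 6C+4CP replicate 1 and lost it without 10C replicates 1 (0.113), 2 (0.121) and 3 (0.0647) and 6C+4CP replicates 2 (0.139) and 3 (0.127).

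Over probe sets limma called 109 of 45037, 67 higher and 42 lower, of which 103 ranged over at most 0.01. Because such calls rest on the last digits of shrunk values, the test was repeated on the varying probe sets, a choice made after seeing the data. Among 5057 genes with a varying probe set limma then called 2, Spc25 (adjusted p = 0.0448) and Sec23a (0.0462), both higher, and 47 at an adjusted p under 0.1. At an unadjusted p under 0.05 there were 730 such genes, 430 higher and 300 lower, against 253 expected by chance. The diets did not overlap in 552 higher and 447 lower genes, 19.8% against 10% by chance. Genes may move together, so these chance values do not show how far such counts vary between groupings of the mice. Other splits of the 6 mice into 3 and 3 gave 43 to 626 genes at that p. The rank product, which ranks pairwise ratios, called 53 higher and 45 lower. Without each mouse in turn limma called 0 (10C replicate 1), 3 (10C replicate 2), 21 (10C replicate 3), 0 (6C+4CP replicate 1), 4 (6C+4CP replicate 2) and 0 (6C+4CP replicate 3) of these genes.

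Next in line by the smallest p without overlap, and not past the threshold over the varying genes, were Usp2 (0.79, adjusted p = 0.0547), Rnf24, a RING finger protein (0.60, 0.0824), Erbin (0.52), Gemin2 (0.60), Cobll1 (0.71), Bcl2l13 (0.55), Hnrnpdl (0.47) and Osbpl11 (0.39, 0.0824) with higher values. Hnrnpdl had 2 further varying probe sets lower and 1 higher. With lower values were Edem1 (-0.54, 0.0547), Appl1 (-0.39), Slc43a1, an amino acid transporter (-0.51), Hspa5 (-1.15), Ifi47, an interferon-induced GTPase (-1.31), Cyp26a1, which degrades retinoic acid (-0.66), Dnajc3 (-0.80), B3galt1 (-1.46), Tars, the threonyl-tRNA synthetase (-0.52), and Fermt2, an integrin activator (-0.69, adjusted p = 0.0972). Singled out after their values were seen, Nnmt, which methylates nicotinamide, differed by -1.74 (SE 0.33) and Egfr, the epidermal growth factor receptor, by -1.24 (SE 0.21). Both were called lower by the rank product over all genes, shrunk ones included.

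**Figure D3:**
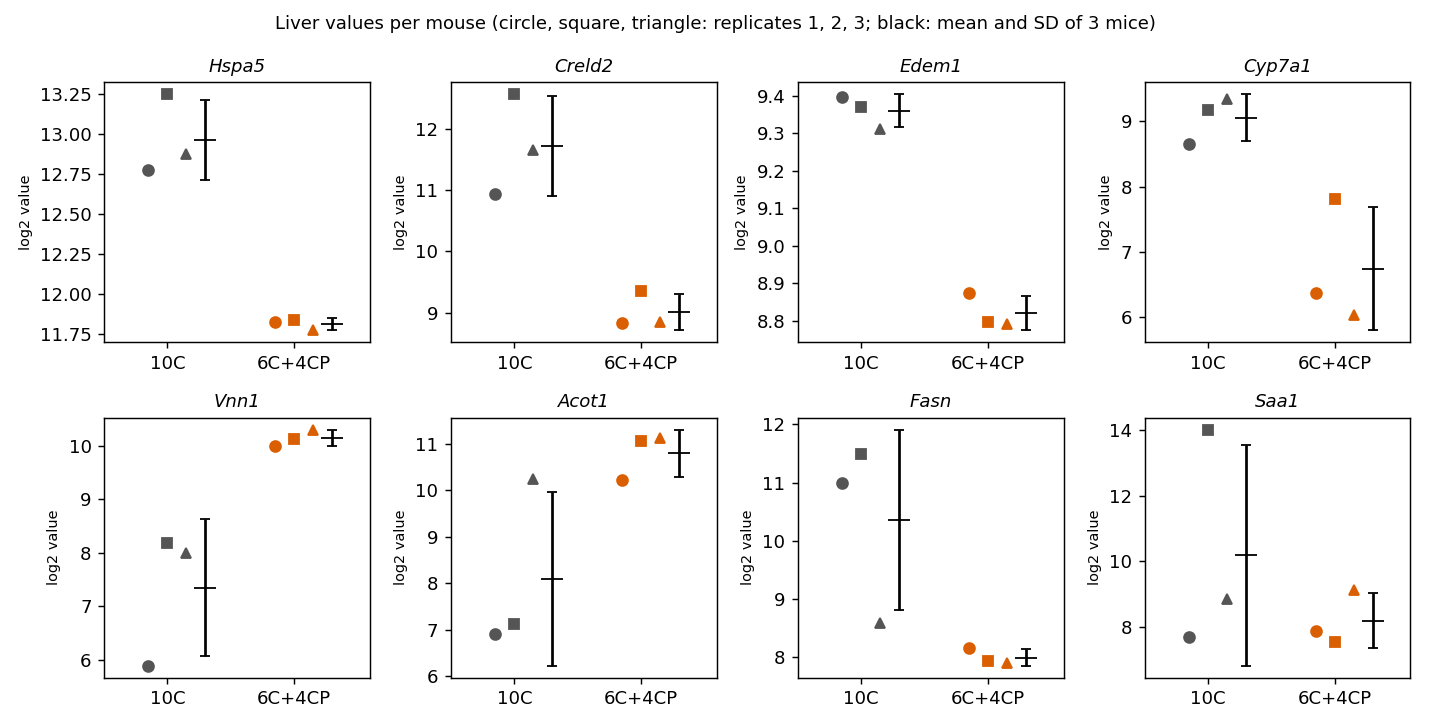
Log2 values (y axis, not starting at 0) of 8 genes in the 3 mice of each diet (x axis), with replicates 1 to 3 as circle, square and triangle and the mean with its SD in black. Hspa5, Creld2, Edem1, Cyp7a1 and Vnn1 do not overlap between the diets, while 1 mouse fed 10C lies near the 6C+4CP values for Acot1 (10.25) and Fasn (8.59) and 1 stands apart for Saa1 (14.03).

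RNA quality was read from array controls that probe the 3' and 5' ends of the same transcript. The 3' minus 5' difference of Actb was 1.23 ± 0.045 (SD, n = 3) in 10C and 1.36 ± 0.29 in 6C+4CP (exact permutation test, two-sided, p = 0.8). For Gapdh it was 0.27 ± 0.046 and 0.33 ± 0.25 (n = 3, exact permutation p = 1). In both controls 6C+4CP replicate 2 was highest, with 1.69 for Actb and 0.62 for Gapdh. Of 3 probe sets for 18S ribosomal RNA, 1 was higher in all 6C+4CP mice than in any 10C mouse (difference 0.40, exact permutation p = 0.1, the smallest that 3 against 3 allows), and the other 2 differed by 0.29 (p = 0.7) and 0.23 (p = 0.5) in exact permutation tests.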

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

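Alternatives on varying probe sets were chosen after the results were seen, and the others before. The log2(value + 16) alternative was not run, since the deposited values are logarithms already. Replicate numbers do not pair the mice, since deviations of same-numbered mice from their diet's mean correlated by 0.477, -0.0893 and 0.0847, and not every mouse correlated best with its own number. With the replicate number as a block limma called 3 probe sets and 2 genes and camera 5 lists, and on varying probe sets 0 and 0. With the block the lipoprotein (adjusted p = 0.12) and urea cycle (0.0983) lists lost their calls and the Kupffer cell list gained one (0.0153). Low signal limits the values, since 4.67% of the dimmest and 46.9% of the brightest of 4 groups of probe sets varied.

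The 109 called probe sets and 46 called genes depend on the processing, and most of them are shrunk values that differ in their last digits. The 4 varying called genes also lost their calls in the settings below that left 0 genes. Quantile normalization left 1 probe set and 0 genes, and median centring 0 and 0. The brighter part of the probe sets, an intensity trend with robust estimation, and a minimum fold of 1.2 left 0 of both. The mean of a gene's probe sets left 0 genes. Leaving out 1 mouse raised the counts to between 285 (10C replicate 1) and 398 (10C replicate 2) probe sets and between 109 and 160 genes (the same mice). The rank product called 887 probe sets and 380 genes. At an unadjusted p under 0.05 limma gave 2890 probe sets and 1299 genes.

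On varying probe sets limma called 0 probe sets (1140 at an unadjusted p under 0.05) and 2 genes, and 6 probe sets at an adjusted p under 0.1. Without any 1 mouse it called 0 varying probe sets in each of the 6 fits, and between 0 and 21 genes (0, 3 and 21 without 10C replicates 1, 2 and 3, and 0, 4 and 0 without 6C+4CP replicates 1, 2 and 3). With an intensity trend it called 0 probe sets and 1 gene, among probe sets ranging over 0.1 it called 1 and 1, and a plain test called 0 and 0. The rank product called 98 genes with a varying probe set.

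Of lists, median centring called 10, 7 as higher and 3 as lower, and the higher calls may follow from its offset of shrunk genes. Fry called 1 for a shift in 1 direction and 11 in either direction, and camera with an estimated correlation 0 (2 at an unadjusted p under 0.05). On varying genes the estimated correlation gave 0 (1 at an unadjusted p under 0.05) and fry for a shift in 1 direction gave 1, as lower, while its 1 call on all genes was higher. The other settings called 4 to 9 lists. Of 35 lists with a varying member, the number of members called over the list alone was alike on varying genes in 23, larger in 9 and smaller in 3. The endoplasmic reticulum, fatty acid oxidation and interferon lists kept direction and call in every camera setting with the preset correlation. Of the alternatives of single lists chosen beforehand, 491 kept their side of the threshold, 28 fell under it, 25 rose past it and 2 reversed.

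The 2 lists that reversed were the cytosolic ribosome (median 0.010255) and the mitochondrial respiratory chain (median 0.016415), both under quantile normalization. Of 2342 such values of single genes 18 reversed, all of them in genes called at differences of at most 4e-09. Under quantile normalization Ap4m1 gave -0.00018827, Apaf1 -0.00019276, Bex2 -0.00044378, Mmp14 -0.0010019, Nudt3 -0.00071651, Rab11fip3 -0.00074905 and Slc35f1 -5.2798e-05, and under median centring each of these 7 gave -0.00044358. Median centring moves all values of an array by 1 offset, so its reversals follow from the alternative itself, while under quantile normalization the shift differed by gene and the cause was not tested, for the 2 lists either. With the mean of all probe sets Apaf1 gave -1.9294e-15 and Nfkbib 1.0267e-07, and without ambiguous probe sets Fbxw8 gave 3.3333e-10 and Nfkbib 2.0633e-07, where another probe set was used.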

Other observations

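The tests of an acute phase response in 10C replicate 2, of sampling time or feeding state as the whole cause of a list, and of RNA quality, clock genes and lipid lists in 2 mice that depart from their diets were chosen only after those results were seen, as were the splits by lists on varying genes and the limit to varying genes itself.

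Mice of the same diet differed in clock and lipid synthesis genes. In 10C replicate 3, Dbp, an output gene of the circadian clock, was lower than the mean of the other mice of its diet by a departure of -2.66, and in 6C+4CP replicate 2 by -1.40. Arntl, the clock activator now named Bmal1, departed by 0.92 and 0.64 in these 2 mice, and the clock repressor Nfil3 by 0.80 and 1.21. Thrsp, a gene of lipid synthesis, departed by -1.75 and -1.42, Srebf1, a transcription factor of lipid synthesis, by -1.08 and -1.44, and Fdps, of cholesterol synthesis, by -2.91 and -1.65. Other genes of these lists departed in 10C replicate 3 alone or in opposite directions, such as Fasn by -2.65 and -0.094, Acly by -2.34 and 0.11, and Lpin1, a phosphatidate phosphatase, by -2.12 and 1.76. Both mice were lower in 14 of 21 members of the fatty acid and triglyceride synthesis list and in 13 of 17 of the cholesterol synthesis list, against 34.2% of all varying genes. Across members, which are not independent replicates, the departures correlated by r = 0.136 and 0.778 in these lists, under the 0.834 and 0.852 that 95% of random lists of the same size stay under. Igfbp1, an insulin-repressed binding protein, read 11.91 and 11.71 in these mice and 8.53 to 10.24 in the other 4. Across 5057 genes with a varying probe set, which are not independent replicates, the 2 departures correlated by r = 0.41. Over varying probe sets, deviations from the diet's mean correlated by 0.401 in these 2 mice and by 0.477 in 10C replicate 1 and 6C+4CP replicate 1. The deviations of the 3 mice of a diet sum to 0, so these 2 values are not independent. The second therefore does not show that likeness across the diets went beyond this pair.

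A score from the 14 varying clock genes (first component, 52.4% of their variance) was -0.76 in 10C replicate 3 and -0.26 in 6C+4CP replicate 2, against 0.038 to 0.44 in the other 4 mice. With that score as a covariate, the median difference of the cholesterol synthesis list moved from -0.00058 to -0.26 and that of the fatty acid and triglyceride synthesis list from -0.030 to -0.11, over varying members. Leaving out 1 mouse at a time gave medians from -0.28 to 0.17 and from -0.16 to -0.014. The -0.16 came without 10C replicate 3, the mouse with the lowest score, and without 6C+4CP replicate 3 that median was -0.097. Since the score rests largely on 10C replicate 3, these shifts cannot tell the clock score from other traits of that mouse.

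The lower endoplasmic reticulum list may come from the diet or from how the values were made and the mice sampled, and its median of -0.68 over the 31 members with a varying probe set lay outside the central 95% (-0.075 to 0.054) of 10000 lists matched on mean level. That comparison leaves open a summarisation that lets bright probe sets vary more, since drawn members are not correlated as the list's own may be, and the list's call was lost that way (adjusted p = 0.377 with an estimated correlation). An acute phase response in 10C replicate 2, the mouse with high Saa1, was also set against the list. 10C replicates 1 and 3 both lay above all 6C+4CP mice in 20 of the 31 members, against at most 10 members in any other split of these 5 mice. The difference was thus seen in these mice without that mouse. With only 9 other splits, and members that may move together, this count cannot exclude that response as the whole cause. For sampling time or feeding state, the clock score did not take up the difference in these mice. With that score as a covariate the median was -0.68 (bootstrap interval over members -0.86 to -0.33). Camera still called the list (adjusted p = 2.41e-10 at the preset correlation). The bootstrap draws members and not mice, and the preset correlation may understate how members move together. Sampling time or feeding state as the whole cause is therefore not excluded. Without 10C replicate 2 the median was -0.51 (-0.72 to -0.20), and since both intervals hold the bound of -0.34 set for these tests, a part played by either cannot be told apart from the diet.

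The higher fatty acid oxidation list also lay outside its matched lists, with a median of 0.56 against a central 95% of -0.072 to 0.054, which leaves the summarisation open for the same reason (adjusted p = 0.532 with an estimated correlation). With the clock score as a covariate the median was 0.62, with a bootstrap interval over members of 0.42 to 1.07 that stays above the bound of 0.28. Camera still called the list (adjusted p = 2.56e-18 at the preset correlation). The clock score thus did not take up the difference in these 6 mice. As the bootstrap draws members and not mice, and the preset correlation may understate how members move together, sampling time or feeding state is not excluded. Another candidate explanation left open is the diet, a hypothesis found and tested on the same 6 mice. A difference in feeding that leaves the clock genes alone was not tested.

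The like departures of 10C replicate 3 and 6C+4CP replicate 2 were set against RNA quality and sampling time or feeding state. In their values over varying probe sets these 2 mice were the pair most alike across the diets (r = 0.985). In deviations from the diet's mean 10C replicate 1 and 6C+4CP replicate 1 were more alike (0.477 against 0.401). The 3' minus 5' excess of 10C replicate 3 was at most 0.135 of that of 6C+4CP replicate 2 in Actb and Gapdh, under the bound of 0.25. That bound was set after the results were seen. 10C replicate 3 also had the highest 3' minus 5' value of its diet in both controls (1.27 for Actb and 0.306 for Gapdh). Its excess was small, but RNA quality is not excluded. Across the 14 clock genes the departures correlated by r = 0.927, against a median of 0.427 and a 95th percentile of 0.867 in random lists. That test was prompted by clock genes seen to depart alike in these mice and restates it, so a shared difference in sampling time or feeding state stays open. No biological explanation from the design was tested, since the 2 mice belong to different diets.

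The 6 mice allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 109 probe sets against 150 in the highest other split, with 5 of the 10 splits giving as many, and 46 genes against 55, with 3 of the 10. It gave 6 lists against 5 and 730 genes at an unadjusted p under 0.05, among those with a varying probe set, against 626, with 1 of 10 splits as large in each. On genes with a varying probe set it gave 5 lists against 7, with 4 of the 10 splits giving as many. The size of the endoplasmic reticulum list's median was 0.68 against 0.39, and that of the fatty acid oxidation list 0.56 against 0.48, again with 1 of 10 splits as large.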
